A study of Mus musculus with 10 samples.

How the data were processed

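RNA was sequenced from 10 mouse samples labelled as endothelial cells sorted from the aorta by fluorescence-activated cell sorting, 5 from stressed and 5 from non-stressed animals. Per the labels' protocols, RNA was isolated with a PicoPure kit and libraries were made with a TruSeq Stranded kit. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with the mm10 build. Their versions, the annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain. The deposited table holds raw read counts per gene, not normalized, for 48526 Ensembl gene identifiers, of which 48058 matched a gene symbol. The other 468 held 0.0508% to 0.0636% of the counts of a library and were kept. The table names no version of its identifiers; coordinates are from the GENCODE annotation of mm10.

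Groups and replicate numbers were taken from the sample titles. The titles number the replicates within each group; nothing says whether each came from 1 animal or a pool, so p-values measure the spread between these samples. Total counts ran from 18020220 to 38237346 per library. A count of 0 therefore allows a level of up to 0.0785 to 0.166 CPM (counts of a gene per 1000000 counts) per library, taken as 3 counts; such limits cover counting error only. No pair of libraries of a group was a duplicate: their counts differed by a chi-square per degree of freedom of 22.3 to 69.8.

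The deposited counts were tested with edgeR 4.0.16 in R 4.3.3: the default filterByExpr filter (minimum count 10), TMM factors, a design of intercept and group, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. The filter left 13334 genes, which held 99.9% of all counts. The standard error of a log2 fold change is its size divided by the square root of F. CPM values beside a fold change use TMM-scaled library sizes and those of genes described across all libraries the plain total. On simulated counts for stressed against non-stressed over 13334 genes, the test recovered 35.8% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 65.2% of those changed 4-fold, and made 0 false calls. Among genes in the upper part of the expression range it recovered 65.6%, 94.1% and 100%. The simulated counts held 67, 67 and 66 genes changed at these folds. Genes varied independently, and the libraries had no structure besides the groups. These rates of recovery and false calls therefore need not hold for the real libraries.

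Before the data were examined, 28 lists of genes (responses, pathways and endothelial functions) and 16 lists of cell type markers were fixed from textbook knowledge. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with camera at a correlation estimated per list, and with fry. Adjustment ran over the 38 lists with 3 or more tested members. On the simulated counts, a list moved 1.3-fold was called and 0 of 40 unmoved lists were. The simulated genes varied independently of each other. Members of the lists called below had estimated correlations from 0.0851 (glucocorticoid response) to 0.949 (erythroid cells). The simulation therefore cannot show how often lists whose members vary together are called falsely. A further 5 lists of monocyte and dendritic cell genes were written after the data had been seen and are used only in the closing section. Library measures were compared by an exact permutation test (two-sided, 252 assignments, scipy 1.17.1); the smallest p it can give is 0.00794. Marker list levels are means of log2(CPM + 1).

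Genes were named by a rule fixed before the data were examined: the genes with the smallest p in each direction at an average of at least 1 log2 CPM, leaving out unnamed predicted genes and pseudogenes, with at most 5 that do not pass the threshold per direction; up to 4 members of each list that is called or that the design asks about and up to 2 of the others; and 13 genes in every case (Icam1, Vcam1, Sele, Selp, Ccl2, Cxcl12, Fkbp5, Tsc22d3, Per1, Nos3, Pecam1, Cdh5 and Apoe). Some genes that the rule takes are not reported here. Leaving the members of the other lists unnamed was decided after the data were seen; excepted are cell markers chosen after their values were seen, which are said to be so.

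Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, 2 other low-count filters, a robust dispersion, a threshold of 0.1, the replicate number as a block, 1 surrogate variable (sva 3.50.0), leaving out mitochondrial, ribosomal protein and haemoglobin genes, and leaving out each library in turn. Added after the data were seen were a count of over 100 reads of the Y-linked gene Ddx3y, the neutrophil marker level or the erythroid marker level as a covariate, and leaving out the 2 libraries farthest from the others on the first 2 principal components.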

Results

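The series asked how acute mental stress changes gene expression in endothelial cells of the mouse aorta. Stressed animals were exposed for 3 h on each of 3 consecutive days, and aortae were taken afterwards. RNA-seq read counts were given for 5 stressed and 5 non-stressed libraries, all labelled aortic endothelial cells. Total counts were 30415732 ± 6097379 (SD, n = 5) in the non-stressed and 23721725 ± 4636084 (SD, n = 5) in the stressed libraries, a difference within the spread between libraries (exact permutation test, p = 0.0952, adjusted p = 0.611 over 22 library measures). The labels give the strain as ApoE and no more of the genotype. Apoe, the gene of apolipoprotein E, was counted at 14.9 to 28.4 CPM over the 10 libraries and differed little between the groups (log2 fold change -0.20, SE 0.17, adjusted p = 0.950).

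The libraries labelled aortic endothelial cells carried myeloid transcripts at high levels and endothelial transcripts at low ones, in both groups. Lyz2, the lysozyme of myeloid cells, was the most abundant gene, at 15692 to 26748 CPM. Ptprc, which encodes the leukocyte antigen CD45, stood at 2650 to 3019 CPM, Csf1r, the receptor of the growth factor CSF1, at 2323 to 2766 CPM, and Ccr2, the chemokine receptor of inflammatory monocytes, at 1277 to 2204 CPM. Cdh5, which encodes the endothelial junction protein VE-cadherin, had 115 reads over all libraries and 0 to 0.992 CPM. Nos3, the endothelial nitric oxide synthase, had 20 reads in 2 of 10 libraries. Pecam1, which platelets and leukocytes also express, reached 12.2 to 46.8 CPM. Lyz2, Ptprc, Csf1r and Ccr2 were chosen after their values were seen. The mean level of the endothelial marker list was 1.11 ± 0.1005 (SD, n = 5) in the non-stressed and 1.04 ± 0.0539 (SD, n = 5) in the stressed libraries on the log2(CPM + 1) scale. The macrophage and monocyte list stood at 6.68 ± 0.214 (SD, n = 5) and 6.80 ± 0.193 (SD, n = 5). The erythroid list stood at 6.56 ± 0.465 (SD, n = 5) and 7.09 ± 0.878 (SD, n = 5), and the B cell list at 5.34 ± 0.842 (SD, n = 5) and 5.23 ± 0.477 (SD, n = 5). Haemoglobin genes took at most 0.532% of the counts of a library. The share of transcripts from myeloid cells was not measured. Every direction given here is one between libraries so labelled, which carried myeloid transcripts at high levels.

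**Figure D1:**
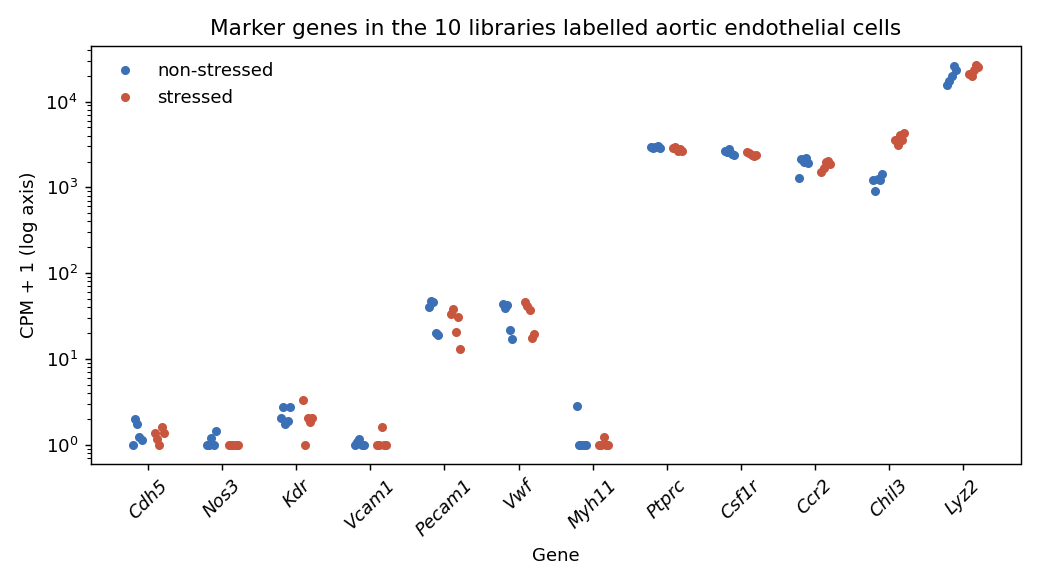
Levels of 12 genes, as CPM + 1 on a log axis, in each of the 5 non-stressed (blue) and 5 stressed (red) libraries, 1 point per library. Ptprc lies between 2650 and 3019 CPM in all 10 libraries, while Cdh5 does not exceed 0.992 CPM.

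Of the 13334 genes tested between these libraries, 1 changed. Chil3, which encodes a chitinase-like protein secreted by myeloid cells (also called Ym1), rose 3.12-fold, from 1196 ± 189 CPM (SD, n = 5) to 3734 ± 470 CPM (SD, n = 5). Its log2 fold change was 1.64 with a standard error of 0.11 (95% interval 1.39 to 1.90, adjusted p = 4.14e-06), and all 5 stressed libraries lay above all 5 non-stressed ones. The gene (ENSMUSG00000040809) lies on chromosome 3 from 106147554 to 106167564, minus strand, in mm10. Chil3 has a near-identical neighbour, Chil4, with which it can share reads; Chil4 had 40 reads in total, but the split of shared reads is not known. The difference of Chil3 between group means of normalized log2 CPM was 1.58 in the 4 libraries with the X-inactivation transcript Xist (2 per group). It was 1.69 in the 6 with over 100 reads of the Y-linked gene Ddx3y (3 per group), here called those with Y-linked transcripts. List medians given below for these libraries are medians of such differences, not of edgeR fold changes. Stressed replicate 5, counted with the 4, also held Y-linked transcripts, at 0.648 CPM. In this fit no gene was lower at the threshold (393 lower at an unadjusted p under 0.05). Other edgeR fits called up to 3 lower, limma-voom 0, and DESeq2, which tested 16598 genes, 5 lower and 14 higher. At an unadjusted p under 0.05 there were 738 genes in all, where chance alone gives 667.

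Several genes separated the groups in every library without passing the adjusted threshold. Tef, a transcription factor of the circadian clock's output, had a log2 fold change of 0.96 (SE 0.16), Vcan, the proteoglycan versican, 1.14 (SE 0.20) and Ptgfrn 1.03 (SE 0.18), each with an adjusted p of 0.156. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, stood at 1.14 (SE 0.23) and Mmp8, the neutrophil collagenase, at 0.71 (SE 0.14), both with an adjusted p of 0.349. In the other direction, Dpp4, a membrane peptidase, had -0.57 (SE 0.10, adjusted p = 0.156), and Dmxl1 and Gbp9, an interferon-inducible guanylate-binding protein, had -0.55 (SE 0.12) and -0.47 (SE 0.10), both with an adjusted p of 0.429. Mga and Setd1b, chromatin regulators, had -0.38 (SE 0.09, adjusted p = 0.547) and -0.29 (SE 0.07, adjusted p = 0.641). Each of the first 5 was higher, and each of the last 5 lower, in all 5 stressed libraries than in any non-stressed one. They were taken for their small p in this same comparison, so the separation is no further evidence. How many genes would separate the groups by chance was not counted. DESeq2 placed 9 of these 10 past the threshold, all but Setd1b. Without a low-count filter 6 of them passed in edgeR, with 1 surrogate variable 5 and with the neutrophil marker level as a covariate 5. Vcan also passed with limma-voom (adjusted p = 0.0491) and without non-stressed replicate 5 (adjusted p = 0.0233). With the replicate number as a block in edgeR, Vcan (adjusted p = 0.0124) and Fkbp5 (adjusted p = 0.0279) passed.

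**Figure D2:**
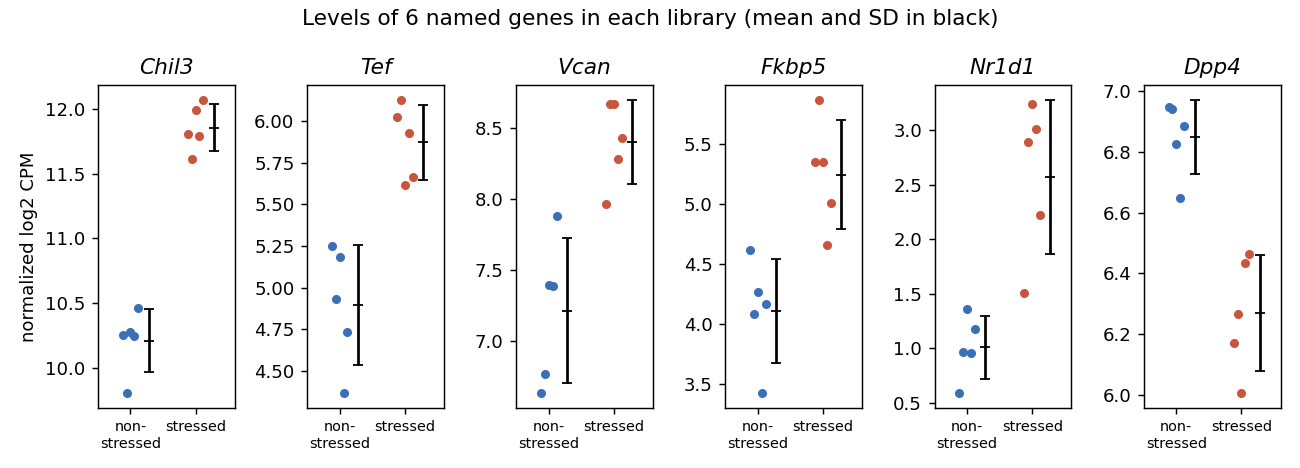
Normalized log2 CPM of 6 named genes in each library of the non-stressed (blue) and stressed (red) groups, with the mean and SD of each group in black (n = 5). Only Chil3, with a log2 fold change of 1.64, passed the adjusted threshold.

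Of the 38 lists tested, camera with the preset correlation called 11, 7 higher and 4 lower in the stressed libraries; 0 held with an estimated correlation and 0 by fry. The circadian clock list had 14 of 15 tested members higher and a median log2 fold change of 0.53 (adjusted p = 5.18e-11; adjusted p = 0.0881 with an estimated correlation). Adjusted over the list alone, 5 members passed, Tef, Nr1d1, Cry1, Nr1d2 and Per3, against 0 over all genes tested in this edgeR fit. DESeq2 placed Tef (adjusted p = 0.000184), Nr1d1 (adjusted p = 0.00740) and Cry1 (adjusted p = 0.0317) past the threshold over all genes. Per3 lies outside the rule for named genes and was chosen after its value was seen. Nr1d1, which encodes the clock repressor REV-ERB alpha, had a log2 fold change of 1.70 (SE 0.37), the repressor gene Cry1 0.53 (SE 0.12), and Nr1d2 0.43 (SE 0.13). Per1, a clock gene that glucocorticoids also induce, had 0.53 (SE 0.23). The list's median difference was 0.20 in the 4 libraries with Xist and 0.68 in the 6 with Y-linked transcripts.

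The glucocorticoid response list had 21 of 22 tested members higher, with a median of 0.25 (adjusted p = 2.32e-06; adjusted p = 0.184 with an estimated correlation). Adjusted over the list alone, Fkbp5 was the 1 member that passed, against 0 over all genes in this edgeR fit. Over all genes Fkbp5 passed with DESeq2 (adjusted p = 0.00392). In edgeR it passed without a low-count filter (0.0106), with the replicate block (0.0279), 1 surrogate variable (0.00544) or the neutrophil covariate (0.0457). The metallothionein gene Mt1 had a log2 fold change of 1.69 (SE 0.70) at low levels. Its means were 1.34 ± 0.865 CPM (SD, n = 5) in non-stressed and 4.33 ± 1.57 CPM (SD, n = 5) in stressed libraries. The phosphatase gene Dusp1 had 0.56 (SE 0.23), Cebpd 0.28 (SE 0.10), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, 0.32 (SE 0.20). The median was 0.18 in the libraries with Xist and 0.31 in those with Y-linked transcripts. Of the immediate early genes, 19 of 22 were higher with a median of 0.34 (adjusted p = 1.19e-05; adjusted p = 0.532 with an estimated correlation), 0 over all genes and 0 adjusted over the list alone; the medians were 0.10 and 0.36. Fos had 0.76 (SE 0.28), Ier3 1.05 (SE 0.37) and Junb 0.45 (SE 0.20). Egr1 had 3.37 (SE 1.08), but stressed replicate 3 held 445 CPM and no other library more than 12.1 CPM; without that library its value was 0.03, those of Fos, Ier3 and Junb were 0.48, 0.61 and 0.16, and the list's median was 0.10 (adjusted p = 0.0291).

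Genes of antigen presentation and of the interferon response lay lower in the stressed libraries. All 7 MHC class II genes were lower, with a median log2 fold change of -1.03 (adjusted p = 8.75e-10, or adjusted p = 0.289 with an estimated correlation). Adjusted over the list alone 6 passed, and 0 over all genes in this edgeR fit. Without a low-count filter edgeR placed Cd74 past the threshold over all genes (log2 fold change -1.04, adjusted p = 0.0345). The invariant chain gene Cd74 went from 1891 ± 1062 CPM (SD, n = 5) to 926 ± 192 CPM (SD, n = 5), a log2 fold change of -1.03 (SE 0.27). H2-Aa had -1.17 (SE 0.34), H2-Ab1 -1.06 (SE 0.30) and H2-Eb1 -1.15 (SE 0.36). The non-stressed libraries spread widely: 2 of 5 stressed libraries lay below all of them for H2-Aa, H2-Ab1 and H2-Eb1, and 3 of 5 for Cd74. At every replicate number the stressed library was lower than the non-stressed one for each of these genes. With that number as a block the list's median was -0.90 (camera at the preset correlation, adjusted p = 1.80e-18). Whether the numbers pair the samples is not known. Without non-stressed replicate 2, which held the highest level of Cd74, the median of the MHC class II list was -0.61 (adjusted p = 9.24e-09), and Cd74 stood at -0.64, H2-Aa at -0.64, H2-Ab1 at -0.61 and H2-Eb1 at -0.61. All 40 interferon response genes were lower with a median of -0.25 (adjusted p = 1.98e-15; adjusted p = 0.532 with an estimated correlation), 15 of them at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. Among them Oas3, an antiviral sensor, had -0.41 (SE 0.10), Trim30a -0.27 (SE 0.09) and Parp14 -0.25 (SE 0.08). The MHC class I list had 17 of 18 members lower with a median of -0.14 (adjusted p = 3.97e-08; adjusted p = 0.477 with an estimated correlation), 0 over all genes and 0 adjusted over the list alone. Tap1, the peptide transporter, had -0.28 (SE 0.09), Nlrc5 -0.34 (SE 0.11) and B2m -0.21 (SE 0.07); H2-Q7, with -0.54 (SE 0.19), shares reads with close relatives and is uncertain. The median differences in the libraries with Xist and with Y-linked transcripts were -0.56 and -1.10 for MHC class II, -0.10 and -0.37 for interferon, and -0.07 and -0.21 for MHC class I.

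**Figure D3:**
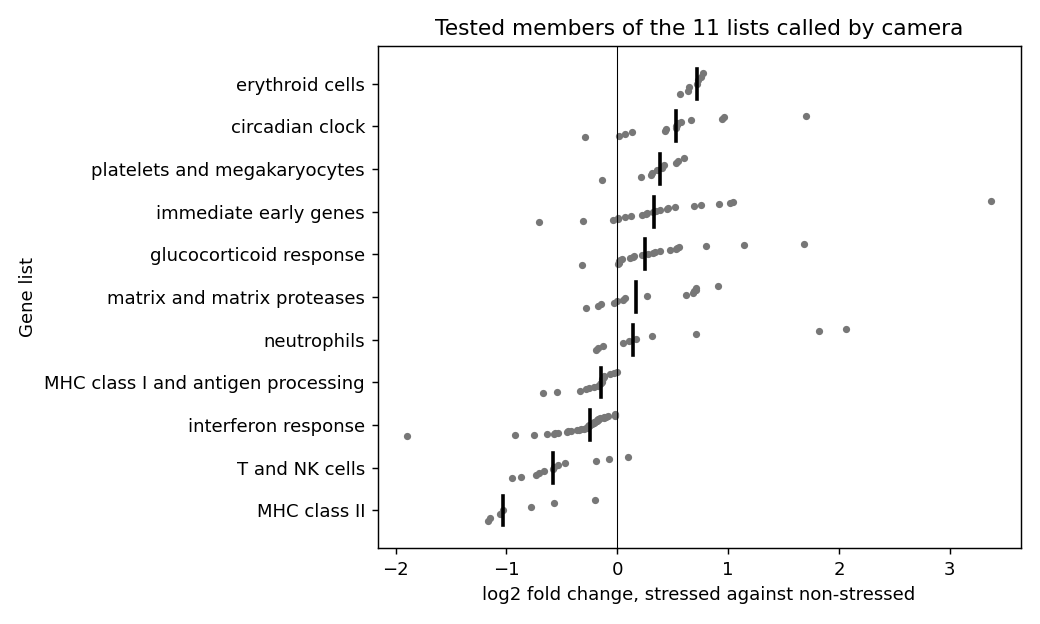
Log2 fold change, stressed against non-stressed, of each tested member (grey points) of the 11 lists called by camera at the preset correlation, with each list's median as a black bar. The medians run from -1.03 for MHC class II to 0.72 for erythroid cells; 0 of the lists held with an estimated correlation.

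The endothelial questions of the series could not be answered from these libraries. They carried myeloid transcripts at high levels, and most of the endothelial genes were near or below detection. Transcripts that were counted, such as Icam1, need not come from endothelial cells. Vcam1, an adhesion molecule for leukocytes, had 20 reads in 3 libraries and the chemokine gene Cxcl12 had 11 reads in 1 library; with Cdh5 and Nos3 they were not tested. Icam1 stood at 160 ± 12.8 CPM (SD, n = 5) and 166 ± 26.8 CPM (SD, n = 5), a log2 fold change of 0.06 (SE 0.10, adjusted p = 0.987). Without stressed replicate 3 it was -0.03. Sele and Selp, the endothelial selectins, had means of at most 2.91 CPM and log2 fold changes of -0.45 (SE 1.14) and 1.305 (SE 0.82); Selp, which platelets also carry, was at 0.23 without stressed replicate 1 and negative with quality weights or with the neutrophil covariate. Pecam1 had -0.36 (SE 0.31). Of the adhesion list, 11 of 16 genes were tested, 6 higher and 5 lower (adjusted p = 0.526), with F11r at 0.91 (SE 0.46), Jam3 at -1.93 (SE 1.21) and Cd34 at -0.81 (SE 0.63). The chemokine list had 7 of 13 tested members higher (median 0.15, adjusted p = 0.490), with Ccl2 at 0.82 (SE 0.56), Cxcl2 at 1.27 (SE 0.73), Ccl3 at 0.61 (SE 0.43) and Ccl9 at 0.15 (SE 0.10). Its median was -0.10 without non-stressed replicate 5, -0.003 and -0.09 without stressed replicates 1 and 2, and 0.21 without non-stressed replicate 4. Of the 5 stressed libraries, 1 lay above all non-stressed ones for Ccl2, 2 for Cxcl2 and 2 for Ccl3. The NF-kappaB list had 11 of 20 members higher (adjusted p = 0.442), with the inhibitor genes Nfkbie at -0.23 (SE 0.08) and Nfkbib at 0.17 (SE 0.10), Nfkb1 at -0.16 (SE 0.06) and Bcl2a1b at -1.11 (SE 0.45). The junction list had 11 of 16 lower (median -0.27, adjusted p = 0.526), with Vegfc at -1.0002 (SE 0.62), Cldn15 at -0.47 (SE 0.35) and S1pr1 at -0.72 (SE 0.56). These 4 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone.

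Markers of other blood cells moved with the groups in camera, also only at the preset correlation. All 7 erythroid genes were higher, with a median of 0.72 (adjusted p = 7.98e-05; adjusted p = 0.666 with an estimated correlation); the haemoglobin genes Hba-a1 and Hba-a2, which are near-identical copies, had 0.76 (SE 0.29) and 0.72 (SE 0.29), Hbb-bs 0.65 (SE 0.30) and Hbb-bt 0.73 (SE 0.33). Without stressed replicate 3 the erythroid median was 0.44 (adjusted p = 0.0181). Haemoglobin genes took 0.2002 ± 0.0550% (SD, n = 5) of the counts in non-stressed and 0.322 ± 0.155% (SD, n = 5) in stressed libraries (exact permutation test, p = 0.135, adjusted p = 0.611). The platelet list had 9 of 10 genes higher (median 0.38, adjusted p = 0.00617; adjusted p = 0.687 with an estimated correlation), with Itga2b at 0.55 (SE 0.34), Pf4 at 0.53 (SE 0.33), Gp1ba at 0.61 (SE 0.44) and Gp9 at 0.42 (SE 0.33). The neutrophil list had 7 of 10 genes higher (median 0.14, adjusted p = 0.0274; adjusted p = 0.687 with an estimated correlation), with Mmp8 passing adjusted over the list alone, Ngp at 1.82 (SE 1.17), Csf3r at 0.17 (SE 0.12) and Camp at 2.07 (SE 1.58). The T and NK cell list had 11 of 12 genes lower (median -0.58, adjusted p = 0.0347; adjusted p = 0.687 with an estimated correlation), with Cd8a at -0.87 (SE 0.57), Cd3d at -0.95 (SE 0.73), Cd8b1 at -0.73 (SE 0.64) and Cd3g at -0.71 (SE 0.65). The matrix and protease list had 10 of 14 genes higher (median 0.17, adjusted p = 0.0237; adjusted p = 0.673 with an estimated correlation), with Mmp8 passing adjusted over the list alone, the basement membrane genes Lamc1 and Col4a1 at 0.69 (SE 0.23) and 0.71 (SE 0.39), and Ctsk at 0.70 (SE 0.56). The last 4 of these lists depended on single libraries, in size and in 2 of them in sign. Those of platelets, neutrophils and matrix genes were not called without non-stressed replicate 4 (medians 0.18, -0.07 and 0.08; adjusted p = 0.147, 0.308 and 0.130) or 5 (0.21, -0.02 and 0.03; adjusted p = 0.163, 0.251 and 0.237), or stressed replicate 1 (0.24, -0.12 and -0.08; adjusted p = 0.120, 0.281 and 0.225) or 2 (0.25, -0.37 and 0.10; adjusted p = 0.0706, 0.414 and 0.153). Medians were 0.62 for neutrophils and 0.64 for matrix genes without non-stressed replicate 1, and 0.67 for platelets without non-stressed replicate 3. With the other libraries left out, medians of matrix genes ran from 0.27 to 0.40, and those of neutrophils were 0.26, 0.26 and 0.29 without stressed replicates 3, 4 and 5; the platelet median was 0.25 without stressed replicate 3. T and NK cells were not called without non-stressed replicate 1 (median -0.36, adjusted p = 0.314), 2 (-0.18, adjusted p = 0.591) or 3 (adjusted p = 0.0720), or stressed replicate 3 (adjusted p = 0.208), 4 (-0.38, adjusted p = 0.376) or 5 (-0.38, adjusted p = 0.429), and their median was -0.87 and -1.05 without stressed replicates 1 and 2. Median differences in the libraries with Xist and with Y-linked transcripts were 1.10 and 0.25 for erythroid cells, 0.88 and 0.15 for platelets, 0.09 and 0.44 for neutrophils, -0.42 and -0.85 for T and NK cells, and 0.34 and 0.49 for matrix genes. Of the 22 library measures, 0 differed by the exact permutation test at an adjusted p under 0.05, with a lowest p of 0.0794. Adjusted over 22 measures, a single measure could not pass even at the smallest p this test can give, 0.00794. The count of 0 therefore says little about whether the groups differ in these measures.

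The other 27 lists tested were not called with all 10 libraries, with adjusted p from 0.0841 to 0.983. Nuclear-encoded oxidative phosphorylation genes were nearest, with 30 of 39 higher and a median of 0.06. The heat shock list had a median of 0.11 (adjusted p = 0.126), the cell cycle list 0.06 (adjusted p = 0.940), the hypoxia and glycolysis list 0.09 (adjusted p = 0.291), the stress hormone receptor list 0.29 (adjusted p = 0.768), the B cell list -0.26 (8 of 8 lower, adjusted p = 0.298) and the endothelial marker list, with 6 of 17 genes tested, -0.12 (adjusted p = 0.298). The median of the endothelial list was -0.045 without non-stressed replicate 2 and -0.45 without stressed replicate 1. Of these 27 lists, 6 were called under another setting. Heat shock was called higher without non-stressed replicate 1 (adjusted p = 0.0157), 4 (0.0159) or 5 (0.0490) or stressed replicate 1 (0.00919), and nuclear-encoded oxidative phosphorylation without non-stressed replicate 5 (0.0369) or stressed replicate 1 (0.00314) or 2 (0.0276). Other omissions went the other way: without non-stressed replicate 3 the heat shock median was 0.04 (adjusted p = 0.766). Adjusted p of nuclear-encoded oxidative phosphorylation reached 0.454 with a library left out. The cAMP and CREB target list was called higher without non-stressed replicate 1 (0.0145) and the mitochondrially encoded proteins without non-stressed replicate 2 (0.0209), and fatty acid and lipoprotein handling lower with the neutrophil marker level as a covariate (0.0170). The B cell list was called lower without non-stressed replicate 4 (median -0.44, adjusted p = 0.00171) and was tested as higher without non-stressed replicate 2 (median 0.07, adjusted p = 0.649). Median, mean and test differed in sign for the adhesion list (median 0.03, mean -0.25, tested as lower), the NF-kappaB list (median 0.00088, mean -0.10, lower), the cholesterol synthesis list (median 0.03, mean -0.04, lower), the shear-responsive list (median 0.02, mean -0.0035, higher), the capillary list (median 0.07, mean -0.0069, higher) and the macrophage and monocyte list (median -0.0022, mean 0.23, higher).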

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

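The tests of a single library standing apart were fixed before the data were examined. In 7 of 190 groups of 5 libraries (95 measures and named genes), 1 library stood apart from the others of its group by Dixon's test; chance gives about 1 in 20, or 9.5 here. Stressed replicate 3 was the library in 3 of them, with the highest normalized log2 CPM of Egr1 (8.81, next 3.61), Junb (10.50, next 9.56) and Mt1 (2.85, next 1.94) among stressed libraries. Mt1 was lowest in non-stressed replicate 1, at -3.76 (next 0.52), which is the value this scale gives to a count of 0. Ccl3 was highest in non-stressed replicate 4, at 4.20 (next 2.71). The macrophage and monocyte list was highest in non-stressed replicate 2, at 7.06 (next 6.63), and H2-Ab1 was lowest in stressed replicate 5, at 7.28 (next 8.04). No explanation was tested for these values. By an interaction test in edgeR between the stress groups and a count of over 100 reads of Y-linked Ddx3y (6 of 10 libraries; stressed replicate 5, with 0.648 CPM of Y-linked transcripts, fell below it), which was chosen after the data were seen, 0 genes passed an adjusted p of 0.05 and 574 had an unadjusted p under 0.05; no other tool was run on it.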

How the results depend on the processing

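The covariates and the omission of the 2 libraries that stand apart (non-stressed and stressed replicate 1) were chosen after the data were seen; the other settings were fixed before. Chil3 was called in all 24 other fits and at a threshold of 0.1, with log2 fold changes of 1.55 to 1.70. The count of genes changed was 19 with DESeq2 (14 higher, 5 lower), 2 with limma-voom (2 higher), 10 without a low-count filter (7 higher, 3 lower), 9 with 1 surrogate variable (7 higher, 2 lower) and 8 with the neutrophil covariate (5 higher, 3 lower). It was 1 to 2 with a library left out (1 to 2 higher, 0 lower), where Vcan joined without non-stressed replicate 5. The replicate block gave 4 genes (3 higher, 1 lower): Chil3, Vcan (adjusted p = 0.0124), Fkbp5 (adjusted p = 0.0279) and, lower, Mrc1. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.128, 0.156, -0.027, 0.118 and 0.124, and 7 of 10 libraries correlated best with their own number. Replicates 1 and 5 of both groups carried Xist (526 and 660 CPM non-stressed, 427 and 441 CPM stressed). Replicates 2, 3 and 4 of both groups had 0 CPM of Xist and 279 to 308 CPM of Y-linked transcripts. Both are hints of pairing from the data and not from the design, and the main test leaves the number out. At camera's preset correlation the block ended no list's call. Followed over the settings were 73 genes: those with the smallest p, those of lists called or asked about, and those named in every case. The naming rule takes 121 tested genes; the other 48, from other lists, were not followed. Of 1746 values, 1743 kept their sign and 32 passed the threshold where the reported value did not. Selp was -0.37 with limma-voom and -0.075 with the neutrophil covariate, and Icam1 ran from -0.033 to 0.12 with a library left out. The cause was not tested.

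The number of lists called was 0 with an estimated correlation and 0 with fry. At the preset correlation it was 9 to 12 with a library left out. With an estimated correlation and with fry, adjusted p was 0.184 and 0.355 for the glucocorticoid response, 0.532 and 0.669 for immediate early genes, 0.0881 and 0.0756 for the clock, 0.532 and 0.669 for interferon, 0.477 and 0.355 for MHC class I, 0.289 and 0.610 for MHC class II, 0.673 and 0.669 for matrix genes, 0.687 and 0.691 for neutrophils, 0.687 and 0.691 for T and NK cells, 0.687 and 0.691 for platelets, and 0.666 and 0.669 for erythroid cells. Both allow for members that vary together. With a library left out, adjusted p ran from 0.000201 to 0.237 for matrix genes, from 1.30e-05 to 0.414 for neutrophils, from 0.000397 to 0.591 for T and NK cells and from 1.60e-07 to 0.163 for platelets. Calls of matrix genes, neutrophils and platelets were lost without non-stressed replicate 4 (0.130, 0.308 and 0.147) or 5 (0.237, 0.251 and 0.163), or stressed replicate 1 (0.225, 0.281 and 0.120) or 2 (0.153, 0.414 and 0.0706). The T and NK cell call was lost without non-stressed replicate 1 (0.314), 2 (0.591) or 3 (0.0720), or stressed replicate 3 (0.208), 4 (0.376) or 5 (0.429). With the neutrophil covariate, adjusted p was 0.357 for matrix genes, 0.834 for neutrophils and 0.0950 for platelets; with the erythroid covariate it was 0.341, 0.276 and 0.621, and 0.723 for erythroid cells. Neutrophil and erythroid lists lose their call there by construction. Platelets stood at 0.0927 without the 2 libraries that stand apart. The NF-kappaB list, not called, ran from 0.163 to 0.946 and was tested as higher without non-stressed replicate 1. Calls were also gained, at the preset correlation: besides those with a library left out, heat shock was called higher with the neutrophil covariate (0.0435) and without the 2 libraries that stand apart (0.000748), nuclear oxidative phosphorylation with the neutrophil (0.00874) and erythroid (0.0454) covariates and without those 2 libraries (0.00926), and fatty acid handling (0.0170) and B cells (0.00158) lower with the neutrophil covariate. With a library left out, B cells ran from 0.00171 to 0.962 and were tested as higher without non-stressed replicate 2; the cell cycle list ran from 0.551 to 0.971 and was tested the other way without non-stressed replicate 3 or 4 or stressed replicate 2, 4 or 5; the stress hormone receptor list ran from 0.618 to 0.863, the other way without non-stressed replicate 5 or stressed replicate 2. With the neutrophil covariate both were also tested the other way (0.839 and 0.846). Other causes were not tested. At the preset correlation, clock, glucocorticoid, immediate early, interferon and both MHC lists were called with each library left out. Neither the estimated correlation nor fry was run with a library left out.

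Library measures past the threshold were 0 with medians of the markers and with each library left out. A single measure could not pass alone in any of these tests, and fewer assignments remain with a library left out. The counts of 0 therefore say little. The B cell difference, -0.11 in log2(CPM + 1), ran from -0.40 to 0.14 with a library left out and was positive without non-stressed replicate 1 (0.05) or 2 (0.14) or stressed replicate 3 (0.07). Genes such as Cdh5 and Nos3 had too few reads in these libraries to be tested.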

Other observations

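The lists of monocyte and dendritic cell genes were chosen after the results were seen. So were the test of neutrophil genes, the weighing of cell identity and the test of time of day. The tests of splits, of B and dendritic cells, and of GC content and length were set before their values were seen. The same holds for the tests of neutrophils for the clock list and of the monocyte programmes. The tests of dendritic cells and of the monocyte programmes used lists chosen after the results were seen. Among 5 lists written after the data had been seen, which are therefore not independent evidence, neutrophil-like monocyte genes had 14 of 17 members higher in the stressed libraries (median log2 fold change 0.48; camera adjusted p = 6.72e-19, or adjusted p = 0.000838 with an estimated correlation and 0.00202 by fry), and classical monocyte genes 12 of 16 (median 0.26; adjusted p = 9.63e-18, or adjusted p = 0.00668 with an estimated correlation and 0.00662 by fry). Dendritic-cell-like monocyte genes had 14 of 15 members lower (median -0.63; adjusted p = 9.56e-14, or adjusted p = 0.0237 with an estimated correlation, but 0.0542 by fry, which did not call the list), and dendritic cell genes 8 of 10 (median -0.45; adjusted p = 0.0133, or adjusted p = 0.175 with an estimated correlation and 0.202 by fry). Non-classical monocyte genes were not called (median -0.07, adjusted p = 0.526).

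A shift between programmes of monocytes, from a dendritic-cell-like towards a neutrophil-like one, stays open. With the genes among the 24 smallest p-values left out, 4 of which the lists held, the mean level of the neutrophil-like list minus that of the dendritic-cell-like list was -3.39 ± 0.575 (SD, n = 5) in non-stressed and -1.94 ± 0.571 (SD, n = 5) in stressed libraries, and all 5 stressed libraries lay above all non-stressed ones (exact permutation test, two-sided, p = 0.00794, the smallest it can give). The lists were written with these data in view, and 6 of the 14 dendritic-cell-like genes are MHC class II genes already reported as lower, so the test largely restates what was seen and decides nothing. With those 6 left out as well, the difference was -2.06 ± 0.657 (SD, n = 5) against -0.78 ± 0.568 (SD, n = 5), 4 of 5 stressed libraries lay above all non-stressed ones (exact permutation test, two-sided, p = 0.0159), and the same limit applies. Neutrophils carried along stay open: S100a8, S100a9, Retnlg, Cxcr2 and Ly6g had a median log2 fold change of -0.12, against 0.48 for the neutrophil-like list, but the interval of their mean difference ran from -1.96 to 2.33.

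Chance cannot be excluded for the number of genes or lists. Of 100 splits of the 10 libraries into groups of 5, the real one included, 8 called at least 1 gene. The real split, which called 1, is among these 8, and the highest other split called 24. For the lists, 32 of the 100 splits, again with the real one among them, called at least 11, and the highest other split called 20. Splits with 24, 17 and 11 genes point to a structure of the samples other than stress, which was not tested. These 3 put replicate 1 of both groups and stressed replicate 2 on the same side, as was noticed after the splits were seen; of the 18 splits that do so, 6 called a gene and 12 called 0, and of the 81 others besides the real split, 1 called a gene. Those 3 libraries had the highest mean levels of the neutrophil list, 5.65, 5.86 and 6.02 in log2(CPM + 1) (next 5.34), and, by a narrow margin, of the smooth muscle list; whether either goes with the calls was not tested. The adjusted p of Chil3 in the real split, 4.14e-06, was below the smallest adjusted p of any gene in the other 99 splits, 0.00368.

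All 10 libraries labelled aortic endothelial cells showed a myeloid profile. Endothelial cells as the main cell type are argued against by the tables: in 0 of 10 libraries did the endothelial list lie above the macrophage and monocyte list. A loss of endothelial transcripts under stress is argued against as well, since 0 of the 5 non-stressed libraries had the endothelial list above. Macrophages resident in the aortic wall as the main cell type are argued against by C1qa, C1qb, C1qc, Cd163, Mrc1 and Lyve1, whose median was at most 0.550% of the Csf1r level in any library. A table of another sorted population under the endothelial label, or a gate that passed leukocytes in every library, could each give the macrophage and monocyte list above in all 10 libraries; they cannot be told apart here, because no sample of another population was analysed.

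At camera's preset correlation, MHC class II and interferon response genes were lower in the stressed libraries; adjusted p was 0.289 and 0.532 with an estimated correlation, and 0.610 and 0.669 by fry. Without non-stressed replicate 2 the median of the MHC class II list was -0.61, against -1.03 with all libraries. GC content and gene length are argued against: the interferon median lay at percentile 0 of 10000 random lists matched on GC content, exon length and expression. In the covariate tests the difference is one of the list's mean normalized log2 CPM, not a median fold change. With the dendritic cell level as a covariate, the MHC class II difference went from -0.74 (95% interval -1.47 to -0.0034) to -0.44 (-1.03 to 0.14). Fewer dendritic cells may account for part of it, but the second interval still holds -0.74, so this stays open. That level comes from a list written after the data had been seen, with 8 of 10 genes lower in the stressed libraries. It also counts genes of dendritic-cell-like monocytes. Fewer B cells stay open: with their level as a covariate the difference was -0.70, with an interval from -1.41 to 0.0011. These covariate tests left the replicate number out. An effect of stress itself on these genes remains open.

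At camera's preset correlation, clock and glucocorticoid response genes were higher in the stressed libraries; adjusted p was 0.0881 and 0.184 with an estimated correlation, and 0.0756 and 0.355 by fry. GC content and gene length are argued against, with the clock median at percentile 100 of 10000 matched random lists. Neutrophils carried along are argued against as well. The clock list's difference in mean normalized log2 CPM was 0.52 without and 0.47 (95% interval 0.23 to 0.71) with the neutrophil level as a covariate. A different time of day at collection and stress hormones cannot be told apart: glucocorticoid genes outside the clock list had a median of 0.22, which both allow, and no label gives the hour of collection. Stress, as the design names it, remains open and is a hypothesis only.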
